A study of Arabidopsis thaliana with 8 samples.

How the data were processed

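Leaf RNA of Arabidopsis thaliana was measured on 8 one-colour NimbleGen arrays labelled with Cy3, 4 from a transgenic line carrying DGTT2 and 4 from the wild type. DGTT2 is a diacylglycerol acyltransferase 2 of the green alga Chlamydomonas, an enzyme of the last step of triacylglycerol synthesis. Per the labels, plants were 6 weeks old and grown on soil at 22 C with 16 h of light and 8 h of dark, the transgenic plants were of line 57, and the 4 RNA samples of each genotype were biologically independent. RNA was extracted with a plant column kit and treated with DNase, per the labels' protocols.

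The authors deposited 1 table of log2 expression values with a row for each of 30361 features, named by locus and gene model, and a column for each array. RMA and Partek are named for it, per the submitters' processing notes; how they were set, the probes behind each feature and the annotation build are not given in the sources used here. The log2 unit was read from the values, which ran from 4.20 to 15.99, with array medians between 10.19 and 10.28. All 8 columns were mapped to a sample by name. All features carry Arabidopsis loci, so the transcript of the algal gene DGTT2 was not measured here, and the genotype labels were not checked against it. RMA summarises several probes per feature and forces the arrays to nearly equal distributions, so a shift of most genes in one direction would not be seen. Values near the upper end may be compressed, which was not measured: 805 features had a mean over 15. No detection calls or background levels were used here, and the number of arrays limits the precision.

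Of the features, 29976 matched a locus of the RefSeq table of assembly TAIR10.1, and 10355 of these had a symbol there; 385 did not match. The table was used only for names, for gene biotypes and for which loci neighbour each other. Since the build behind the array was not stated, no coordinates are given. A planned test of families defined by keywords in product descriptions was not run, because the table used here pairs no descriptions with loci.

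Values were tested as deposited with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, genotype as the only term, two-sided). P-values were adjusted over all 30361 features by the Benjamini-Hochberg method, and a feature was called changed at an adjusted p under 0.05. Confidence intervals of 95% came from the same fit. Before the data were examined, 27 gene lists with 519 members (516 distinct loci) were fixed from general knowledge; all members were on the array. The RefSeq table did not give the symbol used here for the locus in 32 cases, and these members were kept by locus. Lists were tested against all other features with camera at a preset correlation between genes of 0.01, adjusted over the lists. Beside it, camera with an estimated correlation and fry were run, and the difference between genotypes in the list mean per array was tested with an exact permutation test over the 70 assignments of the arrays, whose smallest p is 0.0286.

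Genes named in the text followed a rule fixed before the data were examined. It took the 10 largest rises and the 10 largest falls among called features whose genotypes did not overlap. Where fewer than 10 passed in a direction, it took all of them and then the 5 features of smallest p that did not pass. It always took DGAT1, DGAT2, PDAT1, CER1, CER2, CER3, CER4, CER6, WSD1, SDP1 and WRI1, and from each list the 4 members of smallest p. Features with no symbol were to be printed by locus at most 2 each way. Any other feature named was chosen after its values were seen, and this is said beside it.

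The labels place 4 arrays on each of 2 slides, with 2 arrays of each genotype per slide, so slide was used as a fixed block and each slide was also tested alone. WT arrays were at positions 1 and 2 of both slides and DGTT2 arrays at positions 3 and 4, so position and genotype cannot be told apart. Alternatives were a second quantile normalization, centring on array medians, cyclic loess, leaving out features with a mean below the lower quartile, slide as a fixed or random block, the replicate number as a block, eBayes with trend and robust, array weights, each array left out in turn and other thresholds. The random block (duplicateCorrelation, statmod 1.5.0) was run for features alone, since camera takes no random block; camera was run with the trend setting but not with robust.

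The fits were tested on simulated data with the means and spreads of all 30361 features for the comparison of DGTT2 with WT, with 50 features changed at each of 4 sizes. At an adjusted p under 0.05, 14% of features changed by 0.5 on the log2 scale were recovered, 78% at 1, 94% at 2 and 100% at 3, and 7 of 150 calls were false. Of 20 simulated lists, the 1 shifted by 0.5 was called and none of the others was. Simulated genes were independent of each other, while estimated correlations reached 0.46 in the flavonoid list and 0.82 in the touch and wound list. The simulation therefore does not give the rate of false list calls in the real data. Figures were drawn with matplotlib 3.10.9.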

Results

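Gene expression was measured in leaves of 6-week-old Arabidopsis plants of 2 genotypes, the wild type (WT) and line 57 carrying the Chlamydomonas acyltransferase gene DGTT2, with 4 biologically independent RNA samples each. All DGTT2 samples were of this line, so in every result below an effect of DGTT2 cannot be told apart from other differences between the line and WT. The comparison asks how leaf transcripts differ in a line made to redirect carbon from surface lipids into triacylglycerols, the oil that seeds store and leaves hold little of. Each sample was hybridised to 1 array, and 30361 features, 1 per locus, were given as log2 values. The 8 arrays were close to each other, with correlations across features between 0.988 and 0.995. On the first principal component, with 27.4% of the variance, all DGTT2 arrays lay on one side of all WT arrays (exact permutation p = 0.0286, the smallest that 4 against 4 can give). On the second, with 21.5%, the arrays of slide 1 lay apart from those of slide 2 (exact permutation p = 0.0286).

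Few transcripts were called changed between leaves of the DGTT2 line and WT, 22 of 30361 features. None of them was a member of any of the 27 gene lists, so the lack of calls does not set the lipid lists apart. The pseudogene AT5G35935 was higher in DGTT2, at 10.95 ± 0.08 against 5.22 ± 0.31 on the log2 scale (SD, n = 4 each; adjusted p = 5.5e-07). AT5G35932, a transcribed pseudogene and its direct neighbour, was at 7.94 ± 0.19 against 5.58 ± 0.23 (adjusted p = 0.000387). No fold is given for this pair, since their WT levels were not shown to lie above background. The same limit holds for the log2 differences below of GRP18, DEG3, PAP2, LDOX, AT4G22870, AT5G35940, CYP86A7, PI and FT, each with a genotype mean under 5.95, the median level of pseudogenes. QQS, an orphan gene that affects the starch content of leaves, rose 3.69-fold, from 10.37 ± 0.32 to 12.25 ± 0.16 (adjusted p = 0.0066). UMAMIT17, of a family of amino acid transporters, rose 2.67-fold (log2 difference 1.41, SE 0.19, adjusted p = 0.0434). HDG9, a homeodomain transcription factor, fell by 0.83 on the log2 scale (SE 0.10, adjusted p = 0.0346).

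Among the other named rises, GRP18, a glycine-rich protein of the oleosin-like family of the pollen coat, was higher in DGTT2, at 7.00 against 5.81 (adjusted p = 0.0109). GLC, an acyltransferase-like gene known from fertilisation, was higher by 1.18 (SE 0.16, adjusted p = 0.0434), and NAKR2, of a family of metal-binding proteins, by 1.15 (SE 0.14, adjusted p = 0.0385). The largest falls were in the pseudogene AT5G28993, which fell by 1.28 (SE 0.16, adjusted p = 0.0385), and in AT5G08055, which fell by 1.24 (SE 0.16, adjusted p = 0.0434). DEG3, given as a gene that did not pass, differed by -0.81 (SE 0.12, adjusted p = 0.0672). CSLG3, of the cellulose synthase-like genes, and ABCB13, of the ABC transporters, also passed and were chosen after their values were seen, with log2 differences of 0.89 (adjusted p = 0.0434) and 0.73 (adjusted p = 0.0428).

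**Figure D1:**
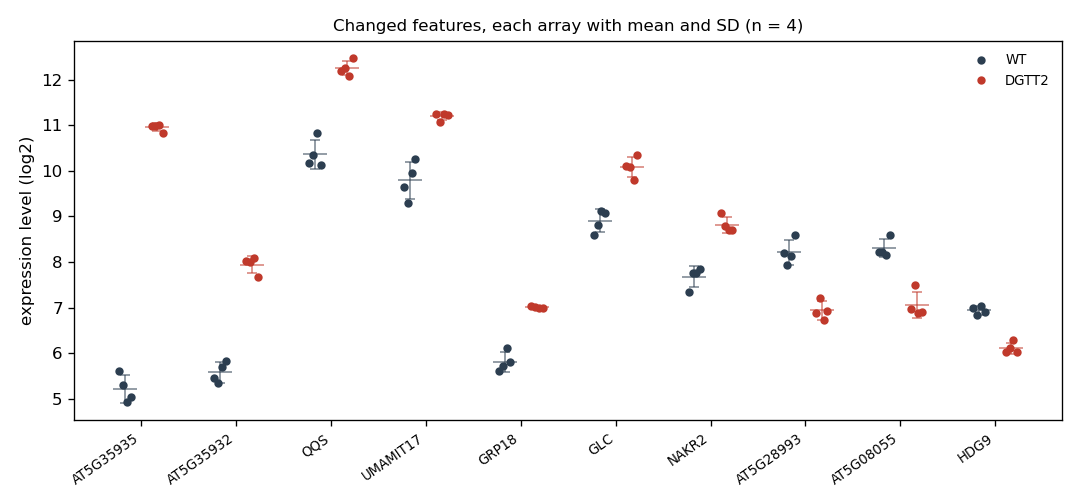
Expression level on the log2 scale (vertical axis) of 10 of the changed features (horizontal axis) on each of the 4 DGTT2 and 4 WT arrays. Points are arrays, and the horizontal marks and bars give mean and SD; in each feature the 4 DGTT2 arrays lay on one side of the 4 WT arrays.

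In all, 22 features were called changed at an adjusted p under 0.05 (limma), 15 higher and 7 lower in DGTT2, and 15 of them differed at least 2-fold (10 higher, 5 lower). Of the 22, 8 were pseudogenes, 5 higher and 3 lower, and 13 were protein-coding. The genotypes did not overlap in any of the 22, nor in 1711 features in all (5.64%, where chance gives 2.86% on average). At an unadjusted p under 0.05 (limma) there were 3194 features (10.5%), 1384 higher and 1810 lower, and 92.9% of all features differed by less than 0.5 on the log2 scale. Other splits of the arrays into 4 and 4 gave between 374 and 2886 features at that p, so such counts vary widely between splits.

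With slide as a fixed block 69 features passed, 27 higher and 42 lower, among them all 22. Each slide alone gave all 22 the same direction, which had to follow, since the genotypes did not overlap in any of them. The log2 differences were 1.64 on slide 1 and 2.13 on slide 2 for QQS and 1.45 and 1.38 for UMAMIT17. Leaving out 1 array moved the count to between 5 (without WT replicate 4) and 39 (without WT replicate 2). Of 19 other settings, AT5G35935 passed in 19, AT5G35932 in 17, QQS in 16, NAKR2 and UMAMIT17 in 8 each, HDG9 in 7 and GLC in 5, and GRP18 in 11 of 18. Without 1 array, 0 of the 17 changed features that the naming rule took moved by over 1.5 times. Of the 122 others that it took, 53 did, so the sizes of small differences given below rest on single arrays in part, and 5 changed direction (DGAT1, PDAT1, CER2, SDP1 and XCP1).

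The plant's own genes of oil synthesis were at like levels in both genotypes. In triacylglycerol and phospholipid assembly, 0 of 27 members passed over all features or adjusted over the list alone (0 at an unadjusted p under 0.05, limma). The 95% interval of each difference lay within 2-fold. DGAT1 and DGAT2, the plant's diacylglycerol acyltransferases, differed by 0.08 (95% interval -0.20 to 0.37) and 0.13 (-0.10 to 0.36), and PDAT1, which makes triacylglycerol from phospholipid, by -0.02 (-0.29 to 0.25). The members of smallest p were PES1 and PES2, phytyl ester synthases of the plastid, at -0.30 (SE 0.14) and 0.45 (SE 0.20), then PAH2 at 0.18 and ATS1 at -0.14. The list's median difference was 0.002 (camera adjusted p = 0.639).

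Fatty acid synthesis likewise had 0 of 32 members passing by either count (0 at an unadjusted p under 0.05, limma), and all 32 intervals lay within 2-fold. KASIII differed by -0.19, PKP-ALPHA by -0.15, BCCP1 by -0.13 and KASI by -0.14. Its median was 0.01, its mean -0.02 and camera's direction down (adjusted p = 0.637). Of the 24 genes of lipolysis, beta-oxidation and the glyoxylate cycle, 0 passed by either count (0 at an unadjusted p under 0.05, limma) and all 24 intervals lay within 2-fold. SDP1, the main lipase of seed oil, was at 0.02 (SE 0.09), PMDH2 at 0.16 and ICL at -0.28 (list adjusted p = 0.452). The 14 genes of plastid membrane lipids had 0 members passing by either count (0 at an unadjusted p under 0.05, limma; list adjusted p = 0.586). FAD8 was at -0.13, FAD4 at -0.10 and DGD1 at 0.08. The 22 lipid droplet proteins and seed oil regulators also had 0 passing by either count (3 at an unadjusted p under 0.05, limma; list adjusted p = 0.842). Among them WRI1, the regulator that turns on fatty acid synthesis in seeds, was at -0.23 (SE 0.10, adjusted p = 0.461), the caleosin CLO3 at 0.32 and the oleosins OLEO3 and OLEO4 at -0.34 and 0.37.

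Genes of the leaf surface showed single differences and no shift of the list. WSD1, an enzyme that makes wax esters and can also make triacylglycerol, was higher in DGTT2 by 1.95 on the log2 scale (8.44 ± 0.57 against 6.49 ± 0.55, SD, n = 4 each). No fold is given, since its WT values (6.04 to 7.19) came near 5.95, the median level of pseudogenes, and were not shown to lie above background. WSD1 missed the threshold over all features (adjusted p = 0.0924) and passed adjusted over the list alone (adjusted p = 0.00585, limma). It also passed with slide as a block (adjusted p = 0.018), with log2 differences of 1.91 on slide 1 and 1.99 on slide 2. CER1-LIKE1, a relative of the alkane-forming enzyme CER1, was at 0.84 (SE 0.21) and passed adjusted over the list alone (adjusted p = 0.0386), but not with slide as a block (adjusted p = 0.0547, SE 0.21). Without the block these 2 were the only ones of 28 wax genes to pass over the list alone, and 0 passed over all features (4 at an unadjusted p under 0.05, limma). CER1 was at 0.17 (SE 0.15), CER2 at 0.01 (SE 0.09), CER3 at 0.11 (SE 0.12), CER4 at 0.35 (SE 0.31) and CER6, which elongates the fatty acids of wax, at 0.08 (SE 0.12). Without WT replicate 2, CER1 was at 0.04, CER4 at 0.11 and CER6 at 0.009. CER1 (means 15.10 in DGTT2 and 14.93 in WT) and CER6 (15.38 and 15.30) lay near or above 15, where values may be compressed. KCS2 was at 0.32 and the wax regulator MYB94 at -0.36. The list's median was 0.004 (camera adjusted p = 0.387), with shifts in its mean of 0.15 on slide 1 and 0.08 on slide 2. For single members moving either way, fry gave an adjusted p = 0.000777. In cutin and suberin 0 of 29 members passed by either count (3 at an unadjusted p under 0.05, limma). LTL1 was at 0.43, CYP86A7 at 0.64, FAR5 at 0.999 and HTH at 0.36 (camera adjusted p = 0.0683).

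Phenylpropanoid and flavonoid genes were higher in DGTT2 as a group. Of 19 members 18 had a higher mean in DGTT2, with a median difference of 0.61, and 11 passed adjusted over the list alone, all of them higher. Over all features 0 passed (11 at an unadjusted p under 0.05, limma). PAP1, the regulator that turns on anthocyanin genes, was at 0.89 (SE 0.17) and its relative PAP2, dim in WT (mean 5.39), at 0.87 (SE 0.18). TT19, which carries anthocyanins to the vacuole, was at 1.81 (SE 0.34), and FLS1, the flavonol synthase, at 0.77 (SE 0.16). The list passed camera with the preset correlation (adjusted p = 2.9e-11) and not with an estimated one (adjusted p = 0.471 with an estimated correlation).

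In this list the means of the 4 DGTT2 arrays lay above those of the 4 WT arrays (exact permutation p = 0.0286, adjusted over the 27 lists 0.257). The lists of antioxidant enzymes and photosynthesis, which camera did not call, separated the arrays in the same way and with the same p. DGTT2 replicate 1 had the highest mean, 0.945 above the average of all arrays, and without it the difference was 0.484 in place of 0.685. The shift was 0.93 on slide 1 and 0.44 on slide 2, and with slide as a block the adjusted p at the preset correlation was 2.0e-10 (without the block, adjusted p = 0.471 with an estimated correlation). The mean of the epidermis and trichome markers differed by 0.11.

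**Figure D2:**
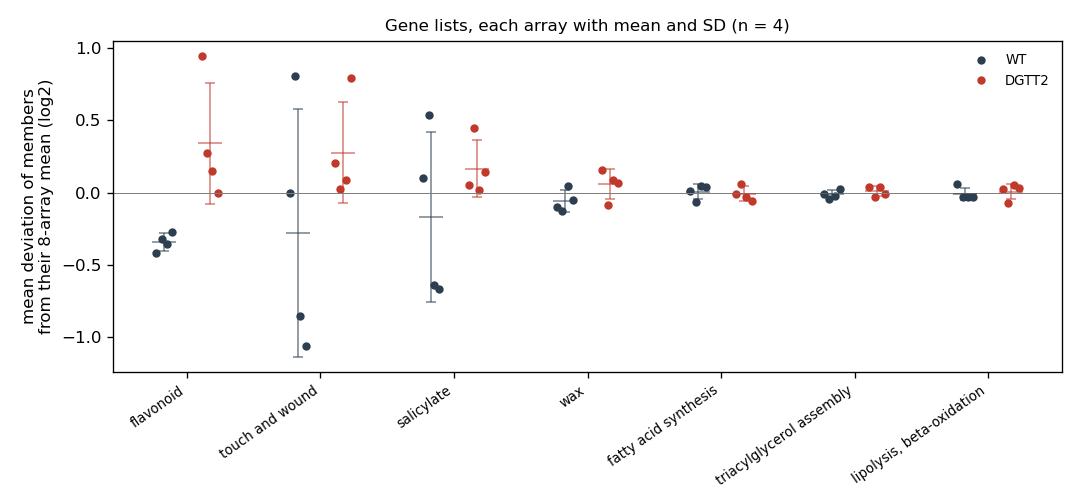
Mean deviation of the members of 7 gene lists from their average over all arrays (vertical axis, log2) on each of the 4 DGTT2 and 4 WT arrays. Points are arrays, and the marks and bars give mean and SD; the flavonoid list separates the genotypes, the touch and salicylate lists spread widely within WT, and the lipid lists lie near 0.

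Genes that respond to touch, wounding and pathogens had a higher mean in DGTT2 and varied more among WT arrays than between the genotypes. In the touch and wound list all 14 members had a higher mean in DGTT2 (median 0.52), and 0 passed by either count (1 at an unadjusted p under 0.05, limma). WRKY40, a regulator of early defence, had a DGTT2 to WT ratio of 2.15 (log2 SE 0.62), with a log2 difference of 0.66 without WT replicate 4. TCH3 was at 0.28 (SE 0.11), ATL31 at 0.87 and ERF6 at 0.57, the last 2 at 0.48 and 0.31 without WT replicate 4. The list means ran from -1.06 in WT replicate 4 and -0.857 in WT replicate 3 to 0.809 in WT replicate 2 and 0.793 in DGTT2 replicate 4 (exact permutation p = 0.229). Camera called the list (adjusted p = 0.00169; adjusted p = 0.644 with an estimated correlation), but not without WT replicate 3 (0.0644) or WT replicate 4 (0.0787). In the salicylate and pathogen list 20 of 25 members had a higher mean in DGTT2 (median 0.29), and 0 passed by either count (1 at an unadjusted p under 0.05, limma). Its means were -0.666 in WT replicate 4, -0.636 in WT replicate 3 and 0.539 in WT replicate 2 (exact permutation p = 0.371). In it SARD1, a regulator of salicylate synthesis, was at 1.27 (SE 0.52), and at 0.65 without WT replicate 2, where it was lowest (10.29) while the list was highest of the WT arrays. ICS1 was at 0.38 and FRK1 at 0.95 (0.20 and 0.54 without WT replicate 4). Camera gave an adjusted p = 0.015 (adjusted p = 0.644 with an estimated correlation). The adjusted p was 0.424 without WT replicate 4, 0.17 without WT replicate 3 and 0.144 without DGTT2 replicate 2.

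Camera with the preset correlation called 4 smaller shifts. Over all features 0 of their members passed (3 glucosinolate, 3 phosphate, 3 flower genes and 1 seed storage gene at an unadjusted p under 0.05, limma). Glucosinolate genes, of the sulfur-rich defence compounds of the cabbage family, had 18 of 19 members higher with a median of 0.09 (adjusted p = 0.005; adjusted p = 0.471 with an estimated correlation), with GSTF11 at 0.60 and FMO-GS-OX1 at 0.38. Phosphate starvation genes had 12 of 16 higher with a median of 0.26 (adjusted p = 0.015; adjusted p = 0.471 with an estimated correlation), with SPX3 at 0.57 and PHO1;H1, of a phosphate exporter family, at 0.52. Flower genes had 9 of 12 higher with a median of 0.18 (adjusted p = 0.0364; adjusted p = 0.546 with an estimated correlation), with PI at 0.56 and FT, the mobile flowering signal, at 0.25. Without features below the lower quartile of signal the flower list's mean shift went from 0.19 to 0.073 and was not called (adjusted p = 0.66). Seed storage genes had all 7 members lower with a median of -0.25 (adjusted p = 0.0275; adjusted p = 0.471 with an estimated correlation). SESA2, a seed storage albumin, at -0.77 (SE 0.14), was the only member of the 4 lists to pass adjusted over the list alone (adjusted p = 0.0031, limma). The seed storage list was dim, with a median level of 6.46 against 5.95 for all pseudogenes, and was not shown to lie above background. Without features below the lower quartile of signal it was still called, with a mean shift of -0.40 (camera adjusted p = 0.0399). With slide as a block, and at the preset correlation, the adjusted p-values were 0.00747, 0.0228, 0.0464 and 0.0228 in this order. Mean shifts on slide 1 and slide 2 were 0.19 and 0.18 for glucosinolates, 0.28 and 0.10 for phosphate, 0.25 and 0.12 for flower, and -0.11 and -0.45 for seed storage. Each of the 4 calls ended when a single array was left out. Glucosinolates were not called without WT replicate 4 (adjusted p = 0.0575), nor phosphate without DGTT2 replicate 1 (0.0958) or WT replicate 3 (0.0695). Seed storage was not called without DGTT2 replicate 4 (0.0854), WT replicate 2 (0.107) or WT replicate 4 (0.0915). Flower was not called without DGTT2 replicate 1 (0.116) or 4 (0.107), nor without WT replicate 1 (0.0578), 3 (0.0695) or 4 (0.176).

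Genes of the circadian clock differed both ways. Morning-phased PRR9, CCA1, RVE8 and LHY were at 0.65 (SE 0.12), 0.54 (SE 0.13), 0.53 (SE 0.15) and 0.56 (SE 0.18). Evening-phased BOA and ELF4 were at -0.58 (SE 0.15) and -0.39 (SE 0.12). These 6 passed adjusted over the list alone. ELF4 and LHY were chosen after their values were seen. Over all features 0 of 21 passed (7 at an unadjusted p under 0.05, limma). Camera found no shift of the list in one direction (adjusted p = 0.387), and fry found change in either direction (adjusted p = 0.000375). With slide as a block 5 members passed adjusted over the list alone, 4 higher and 1 lower, and ELF4 did not (adjusted p = 0.0523, SE 0.13).

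In starch and sucrose metabolism, GBSS1, which makes amylose and is itself under clock control, was at 0.52 (SE 0.12) and was the only one of 31 members to pass adjusted over the list alone (adjusted p = 0.0458, limma). Over all features 0 passed (1 at an unadjusted p under 0.05), and APL1 was at 0.25 (camera adjusted p = 0.481). Photosynthesis genes had 0 of 36 members passing by either count and 1 at an unadjusted p under 0.05 (limma), LHCB1.1 at 0.72 (SE 0.21), with a median of 0.03 (camera adjusted p = 0.202). Of these 36, 32 had a mean over 15, where values may be compressed.

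Among stress and hormone lists not called by camera, jasmonate genes (25 members, adjusted p = 0.0825) had 0 members passing over all features and 1 adjusted over the list alone. This was VSP2, a storage protein induced by jasmonate, at -0.67 (SE 0.15), while PDF1.2A was at 1.35 (SE 0.59). With the replicate number as a block camera did call the jasmonate list (adjusted p = 0.0225), and with slide as a block it did not (adjusted p = 0.106). Among 30 abscisic acid, drought and cold genes (adjusted p = 0.387), the lipid transfer protein LTP4 was at 1.48 (SE 0.49) and KIN1 at -0.54, with 3 higher and 3 lower at an unadjusted p under 0.05. Of 17 senescence genes (adjusted p = 0.202), DIN11 was at 0.89 and SEN1 at -0.43 (-0.265 without DGTT2 replicate 4), the only 2 at an unadjusted p under 0.05. In the 8 antioxidant enzymes (adjusted p = 0.13) CCS was at 0.33, in the 13 heat shock genes (adjusted p = 0.387) HSP70 was at 0.36, and in the 10 genes of endoplasmic reticulum stress (adjusted p = 0.387) BIP3 was at 0.98 (SE 0.62; 0.47 without WT replicate 3). These 3 lists had 0 members at an unadjusted p under 0.05 (limma), and these 5 lists 0 members passing by either count.

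Among markers of tissues other than flower and seed, camera called 0 of 4 lists (0 with an estimated correlation). Epidermis and trichome markers (11 members, adjusted p = 0.586) had 0 members passing by either count (1 at an unadjusted p under 0.05, limma), with GL3, a regulator of trichomes, at 0.69 (SE 0.21). With slide as a block GL3 passed adjusted over the list alone (adjusted p = 0.00654, SE 0.13). Markers of the stomatal lineage (10 members, adjusted p = 0.458) had MYB60, of guard cells, at 0.57 (SE 0.14). Root markers (8 members, adjusted p = 0.42) had CASP1, of the root endodermis, at 0.83 (SE 0.21) and CASP2 at -0.28 (SE 0.12), with mean shifts of the list of 0.35 on slide 1 and -0.15 on slide 2. MYB60 and CASP1 passed adjusted over the list alone, and 0 members passed over all features (limma). Vasculature markers (11 members, adjusted p = 0.615) had 0 passing by either count and SEOR2 at 0.17.

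In all, camera with the preset correlation called 7 of the 27 lists, 6 higher and 1 lower, with 7 called with slide as a block. With an estimated correlation 0 were called (2 at an unadjusted p under 0.05), and fry called 0 in one direction and 5 in either direction. Of the 35 splits of the arrays into 4 and 4, 6 called as many lists, the real one included.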

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

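The tests of the count of changed features, of the share of pseudogenes and of the flavonoid genes (single arrays, epidermis and position) were chosen only after the result was seen. Among the 35 splits of the arrays into 4 and 4, only the real one (1 of 35) called as many features as the genotypes did. It gave 22, against at most 1 in any other. Of the 35 splits, 18 kept the groups equal on each slide, as the real one does. The highest other of these gave 0 features. Since 18 are too few for a share under 0.05, the splits cannot exclude chance for that count. For the lists, 6 of the 35 splits called as many as the real 7, and the highest other called 8, so chance cannot be excluded for the number of lists. The split by slide called 0 features and 1 list.

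Pseudogenes and neighbouring loci stood out among the changed features. Pseudogenes made up 36.4% of the 22 against 14.5% of all features. Changed features were dim, however, with a median level of 7.84, and 2.94% of sets drawn with the same signal held 8 or more pseudogenes. The central 95% of these sets reached up to 8, so the number of pseudogenes may follow from dim features. Same-direction neighbours among the 100 features of smallest p numbered 3, and 3 of the 35 splits had as many, the highest other 6, so neighbouring pairs as such do not set the genotypes apart. In every split, the 385 features not matched to the RefSeq table could not form pairs. They include the changed AT1G65445 (log2 difference 0.96), named after its values were seen, whose locus number is close to that of GLC. Neither test bears on the size of the difference in AT5G35935, and cross-hybridisation of related sequences or a local difference in the genome of line 57 was not tested.

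The higher flavonoid genes in DGTT2 were tested against 3 technical explanations. Leaving out 1 array left a difference of at least 0.484 of the full 0.685, which argues against a single array deciding it. The flavonoid genes exceeded the epidermis and trichome markers by 0.575 (SE 0.159). A larger share of epidermis need not raise both sets equally, however. The markers moved both ways, with 6 of 11 higher in DGTT2 and differences from -0.18 to 0.69, so this does not decide about the share of epidermis. Both slides held both genotypes in equal numbers, so a level shared by all arrays of a slide could not give it. Position stays open: 0 of the positions on a slide held both genotypes, so it cannot be told apart from genotype, and with an estimated correlation the list was not called (adjusted p = 0.471).

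Within a genotype, 1 of the 4 arrays lay apart from the others, by its gap as a share of the range, in 16 of 278 groups of values from 139 genes and in 5 of 54 groups from the lists; chance gives about 1 in 20, or 13.9 of the 278. In DGTT2 the array was replicate 1 for LHCA4 (0.937), replicate 2 for AT5G08055 (0.838), PRR9 (0.918), SESA2 (0.945) and UMAMIT17 (0.919), replicate 3 for DGAT2 (0.904), FAD4 (0.848) and KCS2 (0.882), and replicate 4 for AT5G35935 (0.848) and SEN1 (0.924). In WT it was replicate 2 for NPC5 (0.844) and PAP2 (0.85), replicate 3 for AT1G05740 (0.863), and replicate 4 for AT5G08055 (0.847), CSD2 (0.897) and PAH2 (0.937). Among lists it was DGTT2 replicate 2 for glucosinolates (0.898), DGTT2 replicate 3 for lipid droplets (0.832) and vasculature (0.906), WT replicate 1 for lipolysis (0.933) and WT replicate 4 for epidermis (0.883). AT1G05740, which the naming rule took as a fall that did not pass, has no symbol and goes past the limit of 2 each way. It is printed because all groups found here are given.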

How the results depend on the processing

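All alternatives here were planned before the data were examined, and the causes of the changes were not tested. All 22 changed features kept their direction in every alternative that tested them. Where an alternative only left out arrays this had to follow, since the genotypes did not overlap in any of the 22. Their number moved from 22 (15 higher, 7 lower) to 13 (9, 4) with centring on array medians, 69 (27, 42) with slide as a fixed block, 46 (29, 17) with trend and robust (16 of the 22 and 30 others), 6 (5, 1) at an adjusted p under 0.01 and 118 (48, 70) at 0.1. It was 1 (1, 0) on slide 1 alone and 1 (1, 0) on slide 2 alone, where 2 arrays face 2. A second quantile normalization and cyclic loess each left 4 lower. The random slide block gave 22 (15, 7). Its estimated correlation within slides was -0.034, so small that this fit was nearly the one without a block and says little about slide. Without 1 array the count ran from 5 to 39, the higher ones from 5 to 17 and the lower ones from 0 to 22: it was 7, 6 and 6 without DGTT2 replicates 1, 3 and 4, and 9, 39, 11 and 5 without WT replicates 1, 2, 3 and 4. With the replicate number as a block (the replicate block) 3 features passed, 3 higher and 0 lower, of which all 3 were among the 22. DGTT2 and WT samples of the same replicate number shared a slide and a number in their labels, so they may have been paired. Their deviations correlated by 0.07, 0.20, -0.03 and -0.02, and 1 of 4 correlated best with its own number. This does not decide whether they were paired, so the 3 calls with the replicate block stay a limit on the 22. The slide block added 47 calls, and signal over background was not measured here, so dim features are the least certain.

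The 7 lists became 9 with centring on array medians, 8 on slide 1 alone and 8 with the replicate block. They became 5 without features below the lower quartile of signal, 5 with the trend setting and 4 on slide 2 alone. With an estimated correlation, or with fry in one direction, they became 0. Without 1 array there were 3 to 8, with 3 without WT replicate 3 and 3 without WT replicate 4. Mean shifts with an estimated correlation or fry were those of the preset test: glucosinolate 0.18, flower 0.19, seed storage -0.28, flavonoid 0.68, phosphate 0.19, salicylate 0.33 and touch 0.56. For members moving either way, fry did call the flavonoid (adjusted p = 0.017), seed storage (adjusted p = 0.017) and phosphate (adjusted p = 0.033) lists. It did not call glucosinolate, flower, salicylate or touch. On slide 2 alone the lists of glucosinolates (0.18), flower (0.12) and phosphate (0.10) were no longer called, nor seed storage on slide 1 alone (-0.11). Without features below the lower quartile of signal the flower (0.073) and phosphate (0.18) lists were not called, nor flower (0.19) and seed storage (-0.28) with the trend setting. Without 1 array the shifts ran from 0.12 to 0.24 for glucosinolates, 0.14 to 0.26 for flower, -0.37 to -0.23 for seed storage, 0.48 to 0.80 for flavonoids, 0.12 to 0.22 for phosphate, 0.17 to 0.57 for salicylate and 0.30 to 0.92 for touch. The flavonoid list was called in every camera run at the preset correlation, and not with an estimated one (adjusted p = 0.471). The wax and triacylglycerol lists were called in one direction in no alternative. The random block and robust were not run for lists, and the keyword families were not run.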

Other observations

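The test of further clock genes below was chosen before its values were seen; the features named in the first paragraph were chosen after theirs were seen. With slide as a block, several protein-coding genes passed that did not in the fit without it. BAM5, a beta-amylase, was higher in DGTT2 by 1.52 on the log2 scale (SE 0.22, adjusted p = 0.0431; 0.0852 without the block), PYL6, an abscisic acid receptor, by 0.97 (adjusted p = 0.0423; 0.0924 without) and CSLB03, a cellulose synthase-like gene, by 0.80 (adjusted p = 0.0428; 0.0648 without). MIF2, a small zinc finger gene, fell by 1.23 (adjusted p = 0.0318; 0.324 without), and CYP78A5, a cytochrome P450 of organ growth, fell by 0.73 (adjusted p = 0.0428; 0.241 without). AT4G22870, a locus beside the anthocyanin gene LDOX, was at 2.91 (adjusted p = 0.0428; 0.0705 without), where LDOX was at 1.73 (SE 0.57).

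The loci around AT5G35935 did not share its difference beyond its neighbour AT5G35932. AT5G35930 on the other side of AT5G35932 was at -0.07 (SE 0.11), and AT5G35940 on the far side of AT5G35935 at 0.22 (SE 0.19). The neighbour of UMAMIT17, UMAMIT20, was at 0.86 (SE 0.15, adjusted p = 0.0945). Around QQS the loci beside it, pseudogenes, lay at -0.12 and 0.02. These loci were chosen after their values were seen.

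A candidate explanation for the clock genes is that clock phase at harvest differed between the genotypes, either by sampling time or by the clock itself. In the list of 21, where the pattern was first seen, 8 morning genes averaged 0.364 and 8 evening genes -0.154, which tests nothing by itself. Its members COL1, COL2, CDF1, GRP7 and GRP8 were given no phase and left out of these averages. In 7 further morning and 5 further evening genes the difference was 0.199, in the same direction (exact permutation p = 0.0286, the smallest that 4 against 4 can give), with all DGTT2 arrays above all WT arrays. By these averages it came from the evening genes, at -0.314 (CO at -0.61, COR27 at -0.56), while the morning genes averaged -0.115. The negative morning average rested on RVE2 at -1.41. The other further morning genes lay between -0.14 (CDF3) and 0.50 (LNK3). Harvest times are not used here, so a shift in sampling time and a change of the clock stay open, and the phases were assigned from general knowledge.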
